A study of Mus musculus with 38 samples.

How the data were processed

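The series holds 38 mouse arrays from C57BL/6J animals. DNA of liver tumours induced with the carcinogen diethylnitrosamine (DEN) was compared with DNA of kidney on 26 2-colour Agilent arrays, and RNA was measured on 12 1-colour Agilent arrays. Per the labels' protocols, DEN was given at day 15 of age at 10 µg per g of body weight, tumour DNA carried Cy5 and kidney DNA carried Cy3. Samples were grouped by the genotype in their labels, and arrays with the same animal number in their title were treated as tumours of one mouse. TTD stands for transient telomere dysfunction, induced with doxycycline.

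For 9 of the 14 DNA arrays of the 1x244K design, scanner output was deposited with red and green processed signals, an intensity that the scanner software had background-subtracted and dye-normalized, per the file headers. The same output holds the log10 of red over green, per the file headers, which was checked against the processed signals. These headers name Agilent Feature Extraction 10.1.1.1 for 2 arrays, 10.5.1.1 for 4, 10.7.3.1 for 1 and 9.5.3.1 for 2, with positions on mouse build mm8. Per the submitters' processing notes, Agilent Feature Extraction 10.7.3.1 was used for all 38 arrays and limma, with no version given, for the 26 DNA arrays. At least 99.2% of green and 99.6% of red spots were well above background on each scanned array.

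The authors deposited value tables for all arrays. The deposited 1x244K values are log2 ratios: each of 9 columns equalled the log2 scanner ratio of 1 file times a constant between 0.493 and 1.97, with r rounding to 1. For the other 5 columns the constant is unknown, so a deposited ratio gives no copy number by itself. The 4x44K table holds signed values with medians near 0 in 43020 rows, taken as log2 ratios because of that likeness, and its rows carry numbers without positions or names. In the deposited expression data the values are signed and every probe has a median of 0 over the 6 tumour arrays and again over the 6 liver arrays. They were taken as log2 values, since the log base is not given in the sources used here. Absolute levels are therefore gone, and the table has probe identifiers with no gene names.

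For copy number, log2 of red over green processed signals, or the deposited column, was centred on the median autosomal probe. Control spots were left out of both sources, and spots with an outlier mark were left out of the scanner data only. Repeats of a probe were averaged, which left 220668 autosomal probes. Each chromosome was segmented by penalised least squares with a penalty of 3 times the variance times the log of the number of probes, and at least 10 probes a segment. Segments with a mean of at least 0.2 above or below 0 were called gained or lost. An autosome counted as changed as a whole when 80% or more of its covered length was called in one direction. A pattern shared between arrays was estimated for each array as the median of the others after alignment of sign, and its fitted part was subtracted in an alternative chosen after the data were seen. Groups were compared by a two-sided exact permutation test of the difference in mean with the mouse as the unit. Regions named are whole chromosomes called, called segments under 10 Mb found in at least 2 mice of a group, and 30 loci fixed before the data were examined, of which 28 had a probe with that gene name. Called segments of at least 10 Mb were added after the data were seen. On simulated arrays with the lowest noise of the deposited columns, 19 of 19 planted segments of 50 probes were recovered at 0.5 and 5 of 19 at 0.3, and 1 of 19 segments of 20 probes at 0.5. At the highest noise of the scanner files 0 of 19 segments of 50 probes at 0.5 were recovered. On simulated arrays with nothing planted, at the lowest and highest noise of each source, 0% of the genome was called. Their noise was independent between probes, so this does not test calls that follow a pattern along the genome.

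For expression, 39429 probes were fitted with limma in 4 groups, after 56 control rows had been left out, with Benjamini-Hochberg adjustment at 0.05. The planned choice of 1 probe per gene, the filter on dim probes, the gene lists and the comparison of tumour with liver could not be carried out, because the deposited values hold neither gene names nor levels. The rule for named genes was written before the data were examined: the 5 lowest p in each direction where no probe passes, of which at most 2 per direction are given here, as probe identifiers. In simulated data of the same size, changes of 2 on the log2 scale were recovered for 40% of planted probes in liver, 32% in tumour and 20% in the difference between tissues. False calls numbered 6, 8 and 1 in these comparisons. The simulated noise was independent between probes and arrays, so recovery under variation shared by many probes was not tested.

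The 4x44K arrays could not be segmented without positions, so the planned comparisons of third-generation telomerase-deficient mice, of the 4x44K arrays alone and of both designs together were not made. Counts of segments and of whole chromosomes were compared on the 1x244K arrays in their place. The alternatives tried were other thresholds, penalties, bins of 1 Mb, normexp background correction with an offset of 50 on median signals in place of the planned mean signals, the mouse or tumour as unit, other labels, quantile normalization, array weights and leaving out each animal or array. The number of arrays limits the precision of every comparison. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and data.table (1.17.8).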

Results

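Liver tumours of mice with (TTD+) or without (TTD-) transient telomere dysfunction were compared to ask whether a passing loss of telomere function leaves chromosomal changes in tumours of telomerase-proficient animals. The 1x244K arrays covered 6 TTD+ tumours of 6 mice and 8 TTD- tumours of 6 mice. The 4x44K arrays covered 4 TTD+ tumours, 2 TTD- tumours and 6 tumours of third-generation mTERC-/- mice, which lack the telomerase RNA. RNA came from 3 TTD+ and 3 TTD- tumours, and from 3 TTD+ and 3 TTD- livers taken 48 to 72 h after doxycycline.

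Every one of the 9 scanner files matched the deposited column of another sample, always the one 2 places later in the order of the samples, counted round from the last to the first. The match was exact apart from a constant factor, while the correlation of a file with the column of its own label lay between -0.50 and 0.91. In 4 of the 9 cases the file and its column carried different genotypes. Tumours are therefore named below as the column or the scanner file labelled so, and which label belongs to which tumour is not settled. The columns labelled LT750T1, LT634T4 and LT637T1 ran against most others, with 26 of 91 pairs of columns below an r of -0.3 and the lowest at -0.76. The labels state one dye orientation for all of them, so the direction of change is not settled for these 3 columns.

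**Figure D1:**
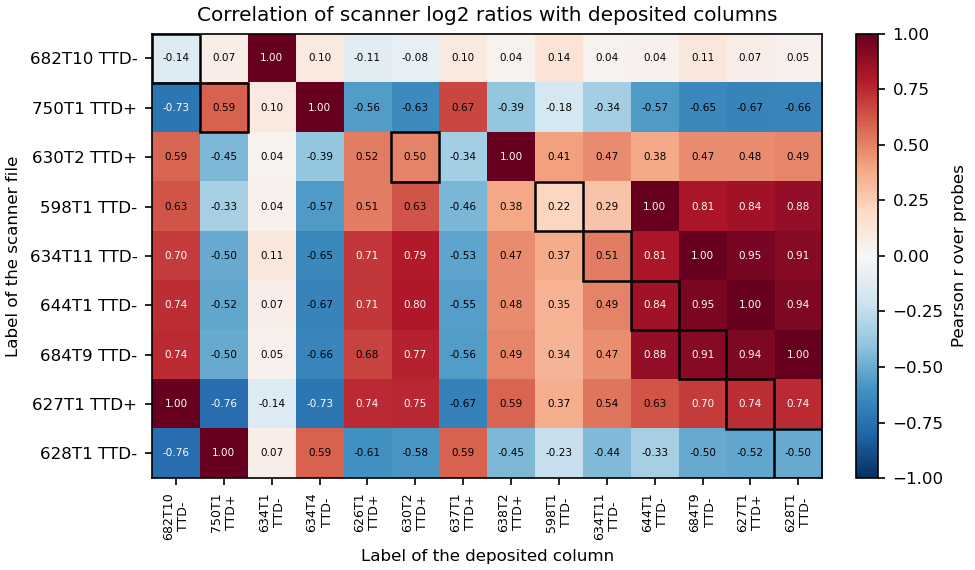
Pearson correlation over probes between the log2 ratios of 9 scanner files (vertical axis) and 14 deposited columns (horizontal axis), with genotypes as labelled; black frames mark pairs with the same label. Each file has 1 column at 1.00, and it is never the framed one.

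The column labelled LT638T2 carried gained distal chromosome 2 and a split chromosome 17. On chromosome 2, positions 160561274 to 181918277 had a mean log2 ratio of 1.33, against 0.03 ± 0.08 (SD, n = 13) in the other columns. Chromosome 17 was gained from 3009074 to 74023094, at 0.66 against 0.01 ± 0.04 (SD, n = 13), and lost from 74023095 to 92974627, at -1.18 against -0.04 ± 0.05 (SD, n = 13). The gained part holds Axin1, a member of the complex that degrades beta-catenin, and Cdkn1a, a cell cycle inhibitor induced by p53. The matching scanner file, labelled LT630T2, gave 0.67, 0.33 and -0.60 for the same segments, and both labels read TTD+. Each deposited column is scaled by a constant of its own, so neither a ratio nor the threshold of 0.2 stands for the same change of copy number in all columns.

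Whole-chromosome changes were called in 2 columns. In the column labelled LT637T1 (TTD+), chromosome 15, which carries the oncogene Myc, had a mean of 0.29 against 0.03 ± 0.07 (SD, n = 13), and chromosome 19 had -0.41 against -0.02 ± 0.04 (SD, n = 13). On the sex chromosomes this column had medians of 0.50 on X and -2.56 on Y, outside all other columns, and whether its tumour and kidney DNA came from 1 animal was not tested. With the sign of this column turned, chromosome 15 would read as lost and chromosome 19 as gained. In the column labelled LT634T11 (TTD-), chromosome 4 was lost at -0.32 against -0.02 ± 0.02 (SD, n = 13), a chromosome that holds Cdkn2a, which encodes cell cycle inhibitors, and Jun, which encodes a transcription factor. The same column had lost chromosome 8 from 98285799 to 132071242, a segment mean of -0.46 that spans Terf2, which encodes a telomere-binding protein. The column labelled LT644T1 (TTD-) had lost the distal end of chromosome 7 from 123743969 to 140358907, at -0.53 against 0.01 ± 0.05 (SD, n = 13), and its scanner file, labelled LT598T1 and also TTD-, gave -0.61.

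Further autosomal segments of at least 10 Mb had column means under 0.3, and none of them still reached 0.2 once a pattern shared between the columns was removed. Of 23 autosomal segments of this length in all columns, 9 still reached 0.2, all of them on the chromosomes named above. Chromosome 15 was gained from 72256514 to 103482674 in the column labelled LT630T2 (TTD+), with a segment mean of 0.25 (0.17 with the pattern removed), and from 73262253 to 103482674 in the column labelled LT634T11, with 0.24 (0.19). The column labelled LT750T1 (TTD+) had segments at 0.22 and 0.27 on chromosome 1 (0.18 each), between 97597993 and 152148932. Its scanner file, labelled LT628T1 (TTD-), showed 1 segment from 55181952 to 197062816 at 0.33. Both readings of chromosome 1 share the unsettled direction of that array. The column is the file times 0.493, so falling short of 0.2 after removal does not attribute these segments to the pattern. With the pattern removed, gains in the file still covered 6.27% of all autosomes, of 7.23% before. The remaining segments lay in the TTD- columns LT634T4 (7, on chromosomes 1, 2, 4, 5 and 15), LT598T1 (chromosome 14), LT684T9 (chromosome 2) and LT634T11 (chromosome 7).

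**Figure D2:**
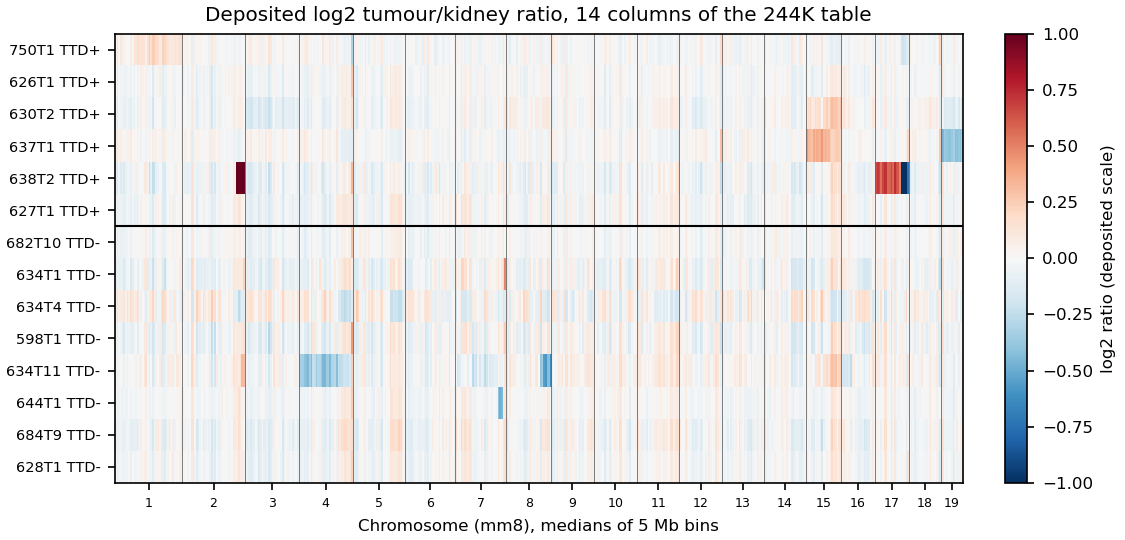
Deposited log2 ratio of tumour over kidney DNA in medians of 5 Mb bins along the 19 autosomes (horizontal axis) for 14 columns (vertical axis, TTD+ above the black line and TTD- below, as labelled); colours end at 1 and -1. The blocks on chromosomes 2 and 17 of column LT638T2, on 15 and 19 of LT637T1, on 4 and 8 of LT634T11 and on 7 of LT644T1 stand out from a weaker striped pattern seen in most columns.

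Few of the 28 loci with probes lay in a called segment, and not all are named here. In addition to Myc, Cdkn2a, Jun, Terf2, Axin1 and Cdkn1a above, the column labelled LT634T1 (TTD-) had gained segments over Axin1, Ccnd1, Fgf15 and Tsc1, the column labelled LT598T1 (TTD-) over Tsc1, and the column labelled LT634T4 (TTD-) had lost segments over Brca2 and Tsc1. Tsc1, an inhibitor of mTOR signalling, was thus called in 3 columns of 2 TTD- mice, gained in 2 and lost in the opposed column LT634T4, whose matching scanner file is labelled TTD+. With the shared pattern removed, Tsc1 lay at 0.22 in LT634T1 but at 0.17 in LT598T1 and -0.12 in LT634T4, and Brca2 at 0.01 in LT634T4, so these last calls were lost. Column LT634T1 had a median r of 0.05 with the others, so the removal could not take out a pattern of its own. Its called segments, 22 in number, covered 2.90% of the autosomes as gains and 0.00931% as losses. Those of at least 3 Mb had means of 0.20 to 0.26. The one over Tsc1 held 236 gene names in 7.99 Mb. Whether these calls are changes of copy number was not tested. Segments over Trp53, Tert, Atm, Met, Braf, Egfr and Mdm2 were called in 0 columns, and their means stayed between -0.13 and 0.14.

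Short changes recurred in 21 autosomal regions of the columns. With the shared pattern removed, every column with the change still reached 0.2 in 3 of them, some columns did in 8 and none in 10. Removal left column LT634T1 nearly unchanged, at 2.91% of the autosomes called both ways. It therefore does not test the calls of that column, which include the region on chromosome 14 below. The 3 kept regions were gains on chromosome 4 from 111566505 to 112109491 in the TTD+ columns LT627T1 and LT637T1 (0.45 to 0.63), the latter of unsettled direction, on chromosome 12 from 88873285 to 88978064, over Adck1, in the TTD- columns LT598T1 and LT634T11 (0.28 to 0.31), and on chromosome 14 from 24197490 to 24591649, over Ppif and Zmiz1, in the TTD- columns LT598T1 and LT634T1 (0.27 to 0.38). The region of chromosome 10 from 78898903 to 81469238, with 127 gene names, was gained in 7 columns of all 6 TTD- mice. Much of it was lost in the opposed TTD- column LT634T4 and called in 4 TTD+ columns, as gained in LT627T1 and LT638T2 and as lost in the opposed LT637T1 and LT750T1. With the pattern removed, the mean of the region still reached 0.2 in 1 of the 7 TTD- columns and in 0 of the TTD+ columns. By the scanner files and their labels, it was gained in 5 TTD- files and the TTD+ file LT627T1 and lost in the TTD- file LT628T1 and the TTD+ file LT750T1. A stretch of chromosome 19 from 38918392 to 40302083, which holds Cyp2c29, Cyp2c38, Cyp2c39 and other cytochrome P450 genes of drug metabolism, was lost in the columns labelled LT630T2 and LT638T2 (TTD+) and LT628T1 and LT634T11 (TTD-), and it was also called in the opposed column LT750T1. A part of chromosome 2 from 85042343 to 89588269, filled with olfactory receptor genes, was lost in the TTD- columns LT598T1 and LT634T11 and gained in the opposed TTD- column LT634T4. With the pattern removed, 0 of the columns with these losses on chromosomes 19 and 2 still reached -0.2.

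The altered share of the autosomes did not separate the genotypes. By the scanner files and their labels it was 2.27% ± 2.30 (SD, n = 3 mice) in TTD+ and 4.64% ± 4.87 (SD, n = 6 mice) in TTD- (difference -2.37, two-sided exact permutation p = 0.512, smallest possible p = 0.0119). By the deposited columns and their labels it was 2.82% ± 2.92 (SD, n = 6) in TTD+ and 2.72% ± 3.27 (SD, n = 6) in TTD- (difference 0.0945, two-sided exact permutation p = 0.939, smallest possible p = 0.00216). Both differences were smaller than the SD of the TTD- mice. With the labels of the matching columns, the scanner files gave a difference of 2.39 in the other direction (exact permutation p = 0.321). Within Feature Extraction versions that held both genotypes, the difference was -9.48 and the exact permutation p of 0.5 was the smallest possible. The matched columns under the scanner labels gave 4.20, where the scanner files of the same arrays under the same labels gave -2.37. Each column is scaled by a constant of its own, so at a fixed threshold the column comparison cannot separate genotype from scaling. The scanner files differed in probe noise (SD), at 0.176, 0.294 and 0.626 in TTD+ and 0.430 to 0.751 in TTD-. In the columns it was 0.346 to 0.371. The files with the largest shares, LT682T10 (12.7%) and LT628T1 (8.35%), had 0.572 and 0.751, but LT627T1 (0.225%) had 0.626. Whether noise moved the scanner comparison was not tested.

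**Figure D3:**
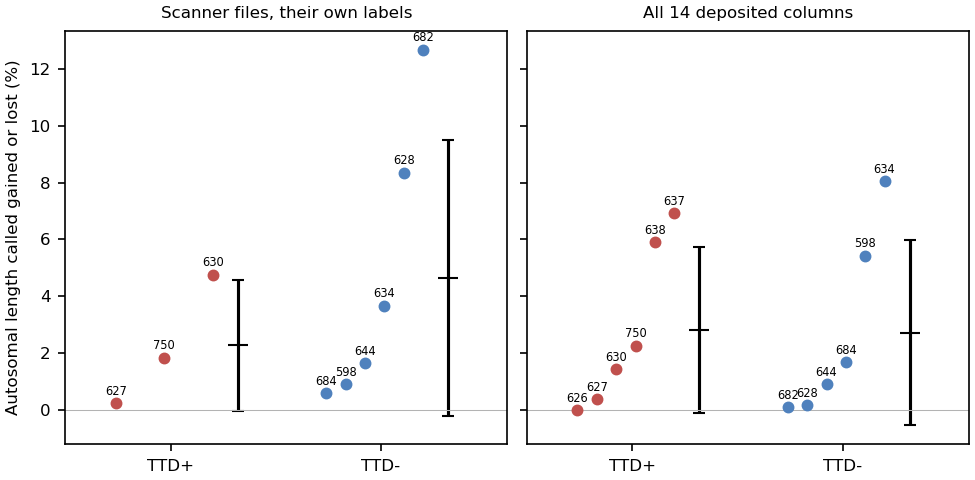
Percent of autosomal length called gained or lost per mouse (vertical axis; points, with animal numbers) in TTD+ and TTD- animals, from scanner files (left) and from all deposited columns (right); the bars beside the points are means with SD. The groups overlap in both panels, at 2.27% and 4.64% on the left and 2.82% and 2.72% on the right.

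Gains and losses were tested apart after the data were seen. In the columns, these shares and the counts of called segments and whole chromosomes carry the same limit from scaling. Gains covered 2.03% ± 1.91 (SD, n = 6) of the autosomes in TTD+ and 0.841% ± 1.12 (SD, n = 6) in TTD- columns (exact permutation p = 0.223), and losses 0.789% ± 1.07 and 1.88% ± 2.18 (SD, n = 6 each; exact permutation p = 0.307). With the 3 opposed columns turned, gains covered 1.39% and 1.01% (exact permutation p = 0.721) and losses 1.42% and 1.71% (exact permutation p = 0.823), with n = 6 each. In the scanner files gains covered 1.51% ± 2.05 (SD, n = 3) in TTD+ and 3.29% ± 4.25 (SD, n = 6) in TTD- mice (exact permutation p = 0.524), the other way round, and losses 0.763% ± 0.644 and 1.36% ± 0.893 (exact permutation p = 0.357). The files labelled LT750T1 and LT628T1 match opposed columns. With both turned, gains covered 1.79% and 2.27% (exact permutation p = 0.881) and losses 0.488% and 2.38% (exact permutation p = 0.25). TTD+ columns had 10.0 ± 10.6 called segments per tumour and TTD- columns 13.6 ± 14.1 (SD, n = 6 mice each; two-sided exact permutation p = 0.669). Whole-chromosome changes came to 0.333 ± 0.816 per tumour in TTD+ and 0.0556 ± 0.136 in TTD- mice (SD, n = 6 each; two-sided exact permutation p = 1), all of those in TTD+ from the column labelled LT637T1.

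Tumours of mTERC-/- mice, in which telomeres are short for life, were measured to set lasting against transient dysfunction, but the 4x44K table carries no positions. A measure without positions was therefore chosen after the data were seen. The percent of its probes beyond 1 on either side of 0 was 5.46% ± 2.38 (SD, n = 6) in mTERC-/- tumours, 5.12% ± 5.07 (SD, n = 4) in TTD+ tumours (two-sided exact permutation p = 0.886, smallest possible p = 0.00476) and 5.04% ± 2.64 (SD, n = 2) in TTD- tumours (exact permutation p = 0.857, smallest possible p = 0.0357). The array labelled DEN_438T1 (mTERC-/-) had 6.39% of probes below -1, and the array labelled LT638T1 (TTD+) had 8.78% above 1. Without LT638T1, the TTD+ tumours had 2.78% ± 2.38 (SD, n = 3) of probes beyond 1 (exact permutation p = 0.155 against mTERC-/-, smallest possible p = 0.0119). Without LT630T1 they had 6.81% ± 4.61 (SD, n = 3, exact permutation p = 0.607), so single arrays moved the difference in both directions. The median absolute deviation lay between 0.304 and 0.326 in all 4x44K arrays. Whether each was scaled by a constant of its own, as the 1x244K columns were, is unknown. Arrays of different genotypes also correlated, as LT634T2 (TTD-) with DEN_452T7 (mTERC-/-) at an r of 0.83. The percent beyond 1 thus does not measure the amount of copy number change.

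In liver 48 to 72 h after doxycycline, which addresses the direct response to dysfunctional telomeres, the probe with the lowest p was lower in TTD+ by a log2 difference of -1.55 (SE 0.28, n = 3 per group). The lowest p among probes higher in TTD+ belonged to a difference of 2.67 (SE 0.58). Both had a limma adjusted p of 1.00. limma called 0 of 39429 probes, with 170 higher and 265 lower in TTD+ at an unadjusted p under 0.05. The groups did not overlap for 4.04% of probes, where chance gives 10%.

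In tumours, the probe A_55_P2082489 was higher in TTD+ by 3.62 (log2, SE 0.46, n = 3 per group, limma adjusted p = 0.320), with means of 2.29 ± 1.13 (SD) in TTD+ and -1.32 ± 0.29 (SD) in TTD- tumours. A_55_P1995175 was higher by 2.60 (SE 0.38, limma adjusted p = 0.490). A_52_P24690 had a difference of -2.48 (SE 0.46) and A_55_P2166486 of -2.39 (SE 0.46), both at a limma adjusted p of 0.998. limma called 0 probes, with 1335 at an unadjusted p under 0.05, of which 579 were higher and 756 lower in TTD+. With array weights the count became 2287, 1131 higher and 1156 lower, under a weight of 157 for the array labelled LT697T3 against at most 1.57 for any other. Quantile normalization called 1 probe, and without the arrays labelled LT752T1, LT634T1 or LT697T3 the counts were 3, 5 and 8.

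The TTD difference in tumours was set against that in liver to ask whether the tissues respond alike. A_55_P2082489 had liver means of 0.06 ± 0.29 (SD) in TTD+ and 0.08 ± 0.15 (SD) in TTD- mice, and its contrast between tissues was 3.63 (SE 0.66, limma adjusted p = 1.00). limma called 0 probes for this contrast, with 798 at an unadjusted p under 0.05. Over all probes, which are not independent replicates, the TTD differences of the 2 tissues had a Pearson r of -0.062 and a Spearman rho of -0.079.

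**Figure D4:**
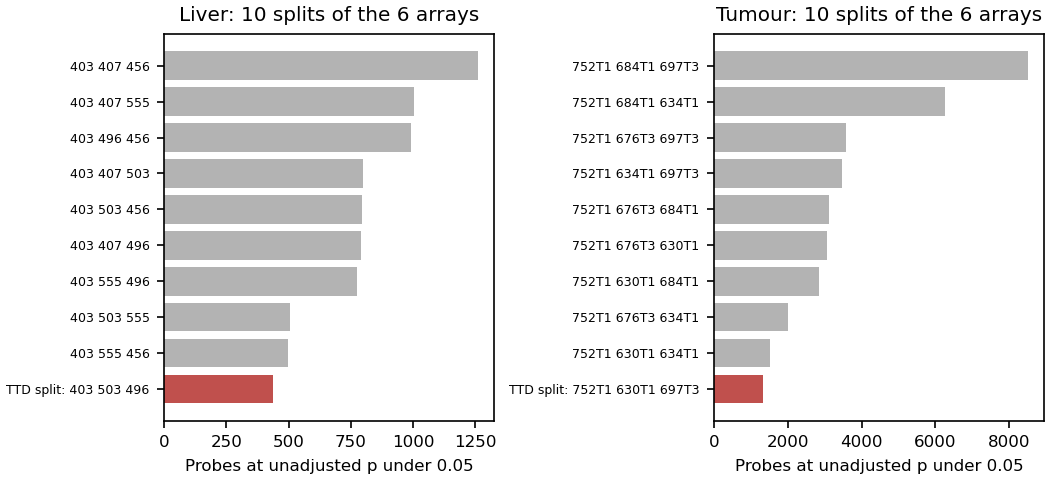
Number of probes at an unadjusted limma p under 0.05 (horizontal axis) for each of the 10 ways to split 6 liver arrays (left) or 6 tumour arrays (right) into 3 and 3, named by one side of the split; the TTD split is in red. It has the lowest count in both tissues, 170 higher with 265 lower in liver and 1335 in tumour.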

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

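In this part the test of one level factor per array was chosen before its result was seen, and all other tests were chosen only after their results were seen. A sample far from the others of its group was looked for in 15 groups, and chance gives about 1 such result in 20 groups.

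Whole-chromosome changes numbered 2 in the mouse of LT637T1 and 0 in the other TTD+ mice, and 0.333 per tumour in the mouse of LT634T1 against 0 in the other TTD- mice. In the column labelled LT637T1 the median log2 ratio was 0.50 on X and -2.56 on Y, against -0.09 to 0.05 and -0.17 to 0.15 in the other TTD+ columns, and these chromosomes entered none of the comparisons. Whether tumour and kidney DNA of that column came from 1 animal was not tested. Over all other columns, TTD- included, X lay between -0.10 and 0.07 and Y between -0.17 and 0.51. The scanner file labelled LT628T1 had a Y median of 0.31, against -0.10 to -0.05 in the other TTD- files.

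The labels of scanner files and deposited columns differ throughout. The distance between a file and its matching column took 1 value over all 9 pairs, which fits a block of labels moved by 2 places in one of the sources. Exchanges between genotypes alone are excluded, since 5 of the 9 pairs join labels of the same genotype. Which source is right cannot be told apart: the 3 columns of the mouse of LT634T1, which should share a kidney reference, had a mean correlation at the 43.4th percentile of all 364 sets of 3 columns, and 1 of the 3 runs in the opposed direction. The biological reading, a difference between TTD genotypes, depends on that choice and stays open.

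A weaker pattern along the genome was shared by most columns. Removing it took away 42.4% of the called length in the 9 columns with an autosomal event of at least 10 Mb before its removal and 7.16% in the 5 other columns, but both pooled values mix columns that behaved differently and support no reading by themselves. Column by column, it took away 97.6% in LT634T4, 97.3% in LT598T1, 87.0% in LT682T10 and 86.6% in LT684T9, where it may account for most calls. In LT750T1 it took away 57.7%, but the matching scanner file, labelled LT628T1, went only from 8.35% to 7.22% of the autosomes. That column is the file times 0.493, with segments close to the threshold, so its 57.7% supports no reading. Removal took away 2.18% in LT637T1, 13.7% in LT638T2, 12.6% in LT634T11 and 15.9% in LT644T1, which argues against the pattern there. It took away 24.1% in LT627T1 and 49.1% in LT628T1, while the called length was nearly unchanged in LT634T1 (2.91% of the autosomes both ways), went from 1.44% to 2.94% in LT630T2 and was 0 in LT626T1; an earlier grouping by the events left after removal had fixed its own outcome and was dropped. With the pattern removed, the altered share was 2.67% in TTD+ and 0.892% in TTD- mice (exact permutation p = 0.212, n = 6 each), which decides neither for nor against the TTD genotype.

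Tumour RNA arrays split in a way unrelated to TTD. The arrays labelled LT752T1, LT684T1 and LT697T3 against the other 3 gave 8526 probes at an unadjusted p under 0.05, and 9 of the other splits gave more than the TTD split, which argues against the TTD genotype as the source. One level factor per array is excluded, since 20.9% of probes stayed under 0.05 after centring each array on its median, of 21.6% before. A level offset that also moves control probes may be involved, in both tissues: 21.8% of tumour probes followed the control profile, against a median of 1.96% for permuted orders of the arrays (permutation p = 0.00417), and 24.2% of liver probes, against 2.24% (permutation p = 0.00694, smallest possible p = 0.00139 for each). The largest axis of variation between arrays followed the control profile with an absolute r of 0.90 in tumours (permutation p = 0.00972). In liver that r was 0.76 (permutation p = 0.0736), so the link is less certain there. What made the offset was not tested.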

How the results depend on the processing

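The alternatives by label, by shared profile, by opposed direction, by median centring, by control probes and by a robust prior, and all those for segment and whole-chromosome counts, were chosen after seeing the data. No paired analysis was possible because replicate numbers only follow the order of the samples. Differences are TTD+ minus TTD-, and the cause of a change was not tested unless given. For the altered share in scanner files the difference of -2.37 became -24.2 with segments called at 0.1 (exact permutation p = 0.0714), 0.168 with segments called at 0.3, 0.406 with normexp and 2.39 with the labels of the matching columns; leaving out 1 mouse gave -3.61 to -0.759. For all columns the difference of 0.0945 became -12.9 at 0.1, -1.24 with each tumour as a unit, -0.570 without the opposed columns and 4.20 in the matched columns with the scanner labels (exact permutation p = 0.0833), where the scanner files under the same labels gave -2.37; leaving out 1 mouse gave -0.727 (without the mouse of LT637T1) to 1.16 (without that of LT634T1), and it was also below 0 without the mouse of LT638T2, LT628T1, LT644T1, LT682T10 or LT684T9 (-0.523, -0.418, -0.267, -0.429 and -0.113). The 4.20 and the -2.37 come from the same arrays under the same labels. Apart from spots with an outlier mark, left out of the scanner data only, files and columns differ by a constant per array. The share called in the columns at a fixed threshold thus depends on that constant, and its difference cannot separate genotype from scaling. Column counts of called segments and whole chromosomes rest on the same threshold. For called segments the difference of -3.56 became -22.5 at 0.1 and -7.5 with each tumour as a unit. It became 1.11 at 0.3, 3.50 in the matched columns with their own labels and 16.2 with the scanner labels. Leaving out 1 mouse gave -7.36 to 0.333 (without that of LT598T1). For whole chromosomes the difference of 0.278 became -0.0833 without the opposed columns and 0 in the matched columns under both labels; leaving out 1 mouse gave -0.0556 (without that of LT637T1) to 0.344. All exact permutation p stayed at or above 0.0714. limma's count in tumours was 1 with quantile normalization and 2287 with array weights, and 0 to 8 when 1 array was left out (3 without LT752T1, 5 without LT634T1, 8 without LT697T3). In liver it was 0 to 4 (4 without LT503Liver), and it stayed 0 for the contrast between tissues. Array weights gave tumour differences of 2.30 for A_55_P2082489, 3.31 for A_55_P1995175, -2.78 for A_52_P24690 and -3.29 for A_55_P2166486. The first was 3.68 with quantile normalization and 3.14 to 4.24 (without LT697T3) when 1 array was left out; the others were 2.32 to 2.95, -2.82 to -2.23 and -2.89 to -1.94. All other alternatives that were run gave 0 probes. The filters on dim probes, 1 value per gene, the trend prior, gene lists and all 4x44K alternatives were not run for lack of levels, gene names or positions.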

Other observations

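All tests in this part were chosen after the results were seen. The column labelled LT630T2 (TTD+) had broad shifts: chromosome 15 had a median of 0.21, of which only the distal part was called, and chromosomes 3 and 19 had medians of -0.11 and -0.10, below the threshold. With the shared pattern removed, its chromosome 15 read as gained from 3091692 to 73804627 at 0.21, a part that holds Myc. Column LT634T11 (TTD-) then also showed a loss on chromosome 16 from 3151162 to 30356165 at -0.20. Events of at least 10 Mb left after that removal came to 1.17 ± 1.17 per TTD+ and 0.333 ± 0.516 per TTD- mouse by column labels (SD, n = 6 each, two-sided exact permutation p = 0.262). In the 9 columns with a matching scanner file they came to 1.33 and 0.2 by column labels (n = 3 and 5, exact permutation p = 0.196). With the scanner labels put on these 9 columns they came to 1.00 and 0.333 (n = 3 and 6, exact permutation p = 0.571). With the shared pattern kept, autosomal events came to 1.5 ± 1.38 and 1.11 ± 1.34 by columns (SD, n = 6 each; exact permutation p = 0.636) and, in the other direction, to 1.33 ± 1.53 and 2.17 ± 3.43 in the scanner files (SD, n = 3 and 6; exact permutation p = 0.893).

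The distal part of chromosome 17 was lost in column LT638T2, from 74023095 at -1.17 after removal of the shared pattern. Column LT750T1, whose direction is not settled and whose scanner file is labelled LT628T1 (TTD-), had a segment from 74393562 at -0.20 after removal, but -0.16 and no call before it. In the scanner file a segment from 74833585 to 91351207 was called at -0.36 with the pattern kept. The column is that file times 0.493, so its missing call before removal does not show that the segment was absent then.

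limma called 0 probes in liver for the TTD split, with 170 higher and 265 lower at an unadjusted p under 0.05, and at most 1 for the 9 other splits (10 of 10 splits reach 0 by definition, and 10 are too few for a share under 0.05). In tumours it called 0, with 1335 at an unadjusted p under 0.05, and at most 30 for the others (again 10 of 10 by definition, and 10 are too few). For the contrast between tissues it called 0, with 798 at an unadjusted p under 0.05, and at most 3 for the others; 100 of 100 splits reach 0 by definition, so these splits do not test chance. With array weights, 2 other tumour splits called 6516 and 4219 probes, more than the 2287 of the TTD split. LT697T3 had a weight of 157 there, against at most 1.57 for any other array, and whether that weight or a structure of the samples made the counts was not tested.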
